A study of Homo sapiens with 52 samples.

How the data were processed

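The series holds RNA-seq, Ribo-seq, TCP-seq and 40S Sel-TCP-seq libraries from HEK293T cells. Groups and replicate numbers were taken from the sample labels, which give 52 samples, and 42 of them have a column in the deposited table. The other 10 samples, in 5 groups of TCP-seq with a vector or with eIF2D put back, were not analysed here, so neither re-expression nor a reversal of KO effects was tested. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

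The values are whole-number counts per transcript, made and deposited by the authors, for 226882 versioned transcript identifiers. Per the labels' protocols, Ribo-seq lysates were treated with cycloheximide and RNase I before ribosomes were pelleted. Per the submitters' processing notes, cutadapt, STAR, featureCounts and Subread were used, without versions, with the builds GRCh38.p13 and hg38. How reads that overlap several transcripts were counted, whether strand was used and whether duplicates or positions were filtered are not given in the sources used here. 218062 transcripts had a count in some library, and these had 190420 distinct count profiles, so 27642 transcripts repeat the counts of another. This is what counting 1 read for every overlapping transcript gives. Transcripts of one gene, and possibly overlapping or antisense genes, are thus likely to share reads, and their tests are not independent. The plan, written before the data were examined, had assumed counts per gene. The same tests were run per transcript.

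No reference genome or table pairing transcripts with genes was used here. The level of the targeted genes could therefore not be checked in any library, the genes and gene lists named in the plan could not be tested, and no coordinates are given. Named transcripts are the 2 largest rises and the 2 largest falls of each comparison among those with an adjusted p under 0.05, the same sign in both clones, siRNAs or reference proteins, and a mean of at least 5 CPM over the libraries of each assay in the fit. The plan had set longer lists for named genes.

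Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM factors, filterByExpr with its minimum count of 10, Benjamini-Hochberg adjusted p under 0.05). Each group was a coefficient, and a comparison was the mean of both clones or siRNAs against the control. Its p-value measures the spread between libraries within groups and leaves out that between clones or siRNAs. A standard error is the size of the log2 change over the square root of the F statistic. Translational efficiency was the interaction of group and assay in one model over RNA-seq and Ribo-seq, for transcripts that passed the filter in both. The 12 TCP-seq libraries shared one model, with each KO set against the wild type libraries of its own run of library names. Wild type libraries of the same run differed by 1.16 and 1.22 times counting noise and those of different runs by 1.62 to 1.81 times, so the runs differ. All other replicate pairs exceeded counting noise too, by at least 1.16 times, and none was taken for a copy of another library. No comparison had 3 libraries in each group, so numbers of calls were not set against other splits of the libraries. The permutation tests of single values per library use all splits and take each library as a unit, also where several come from 1 clone. Each value was measured once, against the mean of the true control libraries, and not anew for each split, so these p-values are approximate.

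Groups of transcripts that share reads were formed by correlation above 0.95 of their replicate deviations over the 42 libraries, led by the transcript of highest mean count. Relations between comparisons used libraries that the comparisons do not share. Contrasts of 2 clones against the same controls do share them, so their agreement is set beside 3 simulated data sets without change. For quartiles of transcripts, the control level or ratio came from libraries outside the comparison. Neither these quartiles nor the likeness between assays was in the plan; both were chosen after the data had been seen, and the quartiles were also run for other comparisons and properties than those reported. Likeness between assays was measured after seeded binomial thinning of each library to the smallest total of its assay.

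The tests were tried on simulated counts drawn from the real means, library sizes and dispersions, with 200 transcripts changed. For TCP-seq (eIF2D KO, 50991 transcripts) 40% of 2-fold and 89% of 4-fold changes were recovered, and 10 unchanged transcripts were called. For eIF2D-V5 Sel-TCP-seq (12135 transcripts) 16% and 88% were recovered. For translational efficiency, 60% and 94% were recovered for the MCTS1 KO (108757 transcripts) and 58% and 92% for DENR depletion (102515 transcripts). In MCTS1 KO Ribo-seq (115412 transcripts) 67% and 90% were recovered and 58 unchanged transcripts were called, 27.0% of all calls. The adjusted p-values were thus too small in that simulated set, and may be so in the real comparison. Unchanged transcripts also exceeded 5% of the calls for siDENR Ribo-seq (10.7%), MCTS1 KO RNA-seq (9.79%), translational efficiency of the MCTS1 KO (8.33%) and of DENR depletion (7.41%), and eIF2D KO TCP-seq (7.19%). These shares depend on how many transcripts change and do not give the share among the real calls.

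The alternatives fixed before the data were examined were RLE factors, library totals alone, DESeq2 1.42.0, no filter on low counts, a mean count of at least 50, the replicate number as a block, each library left out in turn, each clone or siRNA alone, and for TCP-seq no run term and the libraries of 1 run alone. Added after seeing the data were thinning to the smallest total, each distinct count profile once, the wild type libraries of the other run, and Sel-TCP-seq without the second libraries of eIF2D-V5 and MCTS1-V5.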

Results

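Translation was profiled in HEK293T cells, a transformed human embryonic kidney line, after loss of 3 related proteins. eIF2D is a non-canonical translation factor, and MCTS1 and DENR form a complex that resembles it in domain structure. The title of the series places eIF2D in the recycling of the small (40S) ribosomal subunit, which is the removal of that subunit from mRNA. 4 assays were used. RNA-seq measured polyadenylated mRNA. Ribo-seq measured mRNA fragments protected by ribosomes after cycloheximide treatment and RNase I digestion. TCP-seq (translation complex profiling) measures fragments protected by ribosomal complexes, and the ribosome fraction taken for the plain TCP-seq libraries is not given in the sources used here. 40S Sel-TCP-seq measured fragments in small-subunit complexes selected through a V5 tag on eIF2D, MCTS1 or DENR.

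42 libraries in 20 groups were analysed. RNA-seq and Ribo-seq each had 12 libraries, 2 from each of wild type, 2 MCTS1 knockout (KO) clones, control siRNA and 2 siRNAs against DENR. TCP-seq had 4 wild type libraries and 2 from each of 2 eIF2D KO clones and 2 MCTS1 KO clones. Sel-TCP-seq had 2 libraries for each tagged protein. Each comparison took the mean of the 2 clones or siRNAs against its control, and each clone or siRNA was also compared alone. Wild type TCP-seq libraries 1 and 2 served the eIF2D KO, and libraries 3 and 4 the MCTS1 KO, because their library names run on from one another.

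Values were counts per transcript identifier, and the files do not pair these identifiers with gene names or coordinates. Transcripts are therefore given by identifier, at most 2 that rose and 2 that fell in a comparison, the largest changes among transcripts that average at least 5 CPM (counts scaled to the library total) and move the same way in both clones, siRNAs or reference proteins. Library totals were 76967099 to 301214608 counts for RNA-seq, 16370112 to 193940882 for Ribo-seq, 1609303 to 5053637 for TCP-seq and 356019 to 2582917 for Sel-TCP-seq. A read may enter these totals once for every transcript it overlaps, as the repeated count profiles imply, but the counting rule is not given. The 2 libraries of MCTS1 KO clone #1 were the deepest in both RNA-seq (301214608 and 150951436) and Ribo-seq (193940882 and 148159238). The most counted 10 transcripts held 0.97% to 1.63% of a Ribo-seq library and 3.51% to 10.8% of a Sel-TCP-seq library.

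**Figure D1:**
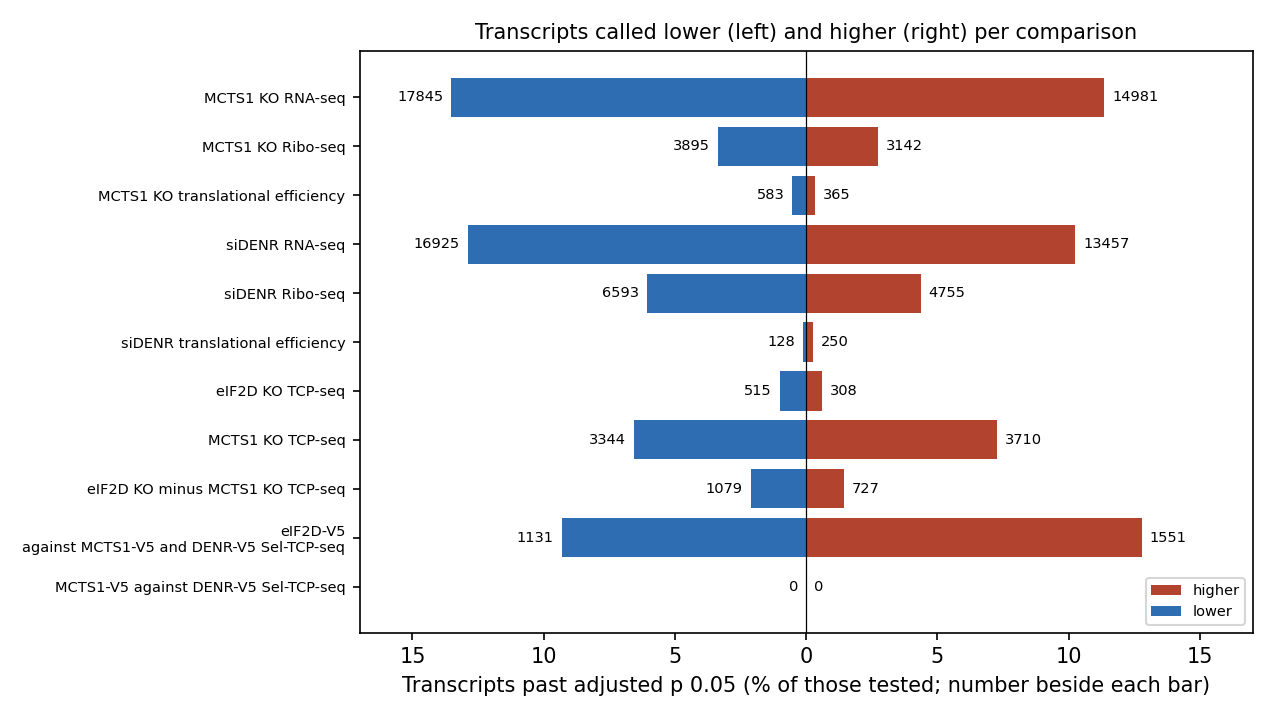
Transcripts past an adjusted p of 0.05 in edgeR's quasi-likelihood test, as a percentage of those tested (x axis), in each comparison (y axis), lower on the left and higher on the right, with the number beside each bar. The bars are longest for RNA-seq in both depletions and for eIF2D-V5 Sel-TCP-seq, and no transcript was called between MCTS1-V5 and DENR-V5.

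Many transcripts differed in mRNA level between the MCTS1 KO clones and wild type, mostly by little. In RNA-seq 14981 transcripts were higher and 17845 lower in the MCTS1 KO than in wild type, of 131951 tested. These calls are for the mean of the 2 clones. Their p-values leave out the spread between clones, so a large change in 1 clone can pass alone. The total of 32826 was 19373 without wild type library 2 and 19290 with DESeq2. The median log2 change of those higher was 0.33 and of those lower -0.31, and 1108 rose and 906 fell at least 2-fold. The clones differed from each other: of 11644 transcripts called in each clone alone, 3415 rose in both, 4309 fell in both and 3920 moved in opposite directions. Independent lists of these sizes would give 2000, 2151 and 4149. Both contrasts share the wild type libraries, which favours the same direction, so independent lists are not the value without change. The changes of the clones correlated with r of 0.15, against 0.58 in simulated data without change (covariances 0.0374 and 0.0302). ENST00000665036.1 and ENST00000666574.1, which have the same counts in every MCTS1 RNA-seq library, showed the largest rise, with a log2 change of 5.10 ± 1.14 (SE, adjusted p = 0.013). That rise lay in clone #1, at 27.1 ± 2.99 CPM (SD, n = 2) against 0.0297 ± 0.00654 (n = 2) in wild type and 0.039 ± 0.0551 (n = 2) in clone #2. ENST00000665036.1 lost the threshold without either wild type library (adjusted p = 0.21 and 0.23), and without library 2 of clone #2 its log2 change was 2.30 (adjusted p = 0.97). The largest falls, of ENST00000413334.1 (log2 change -2.53 ± 0.25) and ENST00000443413.1 (-2.46 ± 0.23), also lay in clone #1, with -4.92 and -4.49 there and -0.14 and -0.43 in clone #2, and each lost the threshold in 4 of the 6 fits with 1 library left out.

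Ribo-seq showed fewer calls than RNA-seq in the same cells. In the MCTS1 KO 3142 transcripts were higher and 3895 lower, of 115412 tested. Of 1428 transcripts called in each clone alone, 561 rose in both, 535 fell in both and 332 moved in opposite directions, where independent lists would give 166, 180 and 345. Here too the wild type libraries are shared, and r between the clones was 0.30, against 0.55 in simulated data without change (covariances 0.0741 and 0.0545). ENST00000493274.5 fell by 3.01 ± 0.11 (SE) on the log2 scale, from 17.9 ± 1.02 CPM in wild type (SD, n = 2) to 2.57 ± 0.135 in clone #1 and 1.93 ± 0.513 in clone #2. ENST00000371315.3 fell from 23.4 ± 1.34 CPM to 4.08 ± 0.1 and 3.07 ± 0.487 (SD, n = 2 each), with an adjusted p of 6.6e-15. ENST00000537022.5 and ENST00000266546.10 rose, with log2 changes of 1.15 ± 0.14 and 1.14 ± 0.11. Across 108757 transcripts, which are not independent replicates, the log2 changes in Ribo-seq followed those in RNA-seq with Spearman's rho of 0.47. Of the transcripts called in both assays, 2279 rose in both, 2607 fell in both, and 92 moved in opposite directions. The count of Ribo-seq calls rested on single libraries: it was 15372 without wild type library 2, and 2535 without library 2 of KO clone #2.

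Translational efficiency, the change in Ribo-seq relative to that in RNA-seq, addressed which mRNAs gained or lost ribosomes per mRNA. In the MCTS1 KO it was higher for 365 transcripts and lower for 583, of 108757 tested. Replicate deviations placed these in 270 and 415 groups of transcripts that share most of their reads. The largest rises were ENST00000413334.1 (log2 change 2.51 ± 0.35, adjusted p = 0.038) and ENST00000443413.1 (2.36 ± 0.26, adjusted p = 0.014). Both came from a lower RNA-seq level in clone #1: ENST00000413334.1 stood at 48.2 ± 3.99 CPM in wild type RNA-seq and 1.47 ± 0.896 in clone #1, while its Ribo-seq level was 27.9 ± 4.29 and 28.3 ± 3.66 (SD, n = 2 each). The largest falls had the opposite make-up. ENST00000442699.1 (log2 change -2.42 ± 0.15) rose in RNA-seq from 1.84 ± 0.093 to 26.3 ± 3.15 CPM in clone #1, and ENST00000452176.2 (-2.39 ± 0.32) from 5.77 ± 0.33 to 129 ± 1.82 CPM (SD, n = 2 each). In clone #2 these 4 transcripts had log2 changes of 0.09, 0.12, -0.66 and -0.10, none past the threshold. With 1 of the 12 libraries left out, ENST00000413334.1 lost the threshold in 9 of 12 fits, ENST00000452176.2 in 8, ENST00000443413.1 in 6 and ENST00000442699.1 in 0. Clone #2 alone gave 131 calls and clone #1 alone 5872, and the count was 4854 without wild type Ribo-seq library 2.

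After siRNA against DENR, mRNA levels differed about as widely. In RNA-seq 13457 transcripts were higher and 16925 lower than with control siRNA, of 131311 tested, and 1106 rose and 893 fell at least 2-fold. Scaled by library totals alone 15782 were higher and 14260 lower, and without control library 1 the total was 14731 instead of 30382. The 2 siRNAs moved transcripts together more than the MCTS1 clones did: of 11773 called with each siRNA alone, 5651 rose with both, 5091 fell with both and 1031 moved in opposite directions, where independent lists would give 1435, 1852 and 3261. The siRNAs also share their control libraries. Their changes correlated with r of 0.47, against 0.49 in simulated data without change (covariances 0.0908 and 0.0294). ENST00000455982.2 fell by 4.11 ± 0.10 on the log2 scale (SE, adjusted p = 2.3e-39). ENST00000280557.11 fell from 31.7 ± 2.7 CPM to 1.45 ± 0.339 with siRNA #1 and 2.74 ± 0.0851 with siRNA #2 (SD, n = 2 each). ENST00000426530.2 and ENST00000326656.12 rose, with log2 changes of 2.17 ± 0.11 and 2.11 ± 0.11.

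In Ribo-seq 4755 transcripts were higher and 6593 lower after DENR depletion, of 108890 tested. The total of 11348 was 5728 without control library 2 and 6342 with DESeq2. ENST00000588411.5 rose from 2.23 ± 0.11 CPM to 13.4 ± 0.0868 with siRNA #1 and 13.8 ± 0.481 with siRNA #2 (SD, n = 2 each), a log2 change of 2.58 ± 0.14 (SE, adjusted p = 9.5e-21), and ENST00000589266.5 rose by as much (2.57 ± 0.16). ENST00000649003.1 and ENST00000647564.1 fell, with log2 changes of -2.06 ± 0.16 and -2.05 ± 0.16, mostly with siRNA #1 (-3.79 and -3.78, against -0.33 and -0.32 with siRNA #2). Changes in Ribo-seq followed those in RNA-seq with rho of 0.54 across 102515 transcripts. Both assays called 2990 transcripts higher and 4741 lower, and 56 moved in opposite directions.

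Translational efficiency after DENR depletion was higher for 250 transcripts and lower for 128, of 102515 tested. ENST00000455982.2 and ENST00000280557.11 rose most, with log2 changes of 3.47 ± 0.17 and 3.04 ± 0.16 (SE). Both are the transcripts that fell most in RNA-seq, and in Ribo-seq they fell less: ENST00000280557.11 went from 17.4 ± 1.34 CPM to 9.46 ± 0.282 and 8.32 ± 2.96 (SD, n = 2 each). Their rise in efficiency thus came with a loss of mRNA and not with a gain in Ribo-seq. Whether they belong to DENR, the siRNA target, could not be checked without gene names. ENST00000588173.1 (log2 change -1.04 ± 0.19, adjusted p = 0.0022) and ENST00000292433.4 (-0.95 ± 0.19, adjusted p = 0.0073) fell most, but had an adjusted p of 0.22 and 0.31 with DESeq2 and lost the threshold in 2 and 4 of the 12 fits with 1 library left out. Of 99 transcripts called with each siRNA alone, 77 were higher and 22 lower with both. The total was 139 without control RNA-seq library 1 and 766 without RNA-seq library 2 of siRNA #1.

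The responses to the loss of MCTS1 and of DENR, which form a complex, were compared. Across 101174 transcripts the changes in translational efficiency had Pearson's r of 0.05 and Spearman's rho of 0.04 between the MCTS1 KO and DENR depletion, 2 experiments with no library in common. Single clones against single siRNAs gave rho from -0.04 to 0.07. The MCTS1 KO clones themselves had r of 0.28 in this measure, against 0.57 in simulated data without change (covariances 0.0592 and 0.0542). With so little shared by the clones, a low rho cannot tell whether the 2 losses act alike. No transcript was called higher in both, where independent lists would share 0.876. 14 were lower in both, in 7 groups of shared reads, where 0.605 would be shared (Fisher's exact test, odds ratio 26.9, BH-adjusted p = 3.5e-15). A further 20 transcripts, in 11 groups, were lower in the MCTS1 KO and higher after DENR depletion (odds ratio 17.4, BH-adjusted p = 1.1e-17). These p-values treat transcripts that share reads as independent and are too small, and they were adjusted over the 40 overlaps tested. In RNA-seq 2559 transcripts rose and 4392 fell in both, where independent lists would share 1521 and 2323. The 3377 that moved in opposite directions lay below independent lists (1719 against 1918 and 1658 against 1842), and rho of the changes was 0.12. Calls lay more often in abundant transcripts. Falls in the highest and lowest quartile of mRNA level numbered 8568 and 1210 in the MCTS1 KO, and 7579 and 1302 after DENR depletion. This alone raises overlaps, which were not matched by counts. In Ribo-seq 306 rose and 663 fell in both, where 135 and 233 would be shared, and those moving in opposite directions also exceeded independent lists (258 against 186 and 269 against 170).

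In TCP-seq, the number of transcripts called after loss of eIF2D depended on the wild type libraries used. Against libraries 1 and 2, 308 were higher and 515 lower in the eIF2D KO than in wild type, of 50991 tested, in 189 and 302 groups of shared reads. ENST00000445983.5 and ENST00000651998.1, with the same counts in every TCP-seq library, rose from 2.63 ± 1.43 CPM to 10.2 ± 0.498 in clone #1 and 11.4 ± 0.35 in clone #2 (SD, n = 2 each), a log2 change of 2.08 ± 0.38 (SE, adjusted p = 2e-04). The same transcripts stood at 1.95 ± 0.118 and 2.56 ± 0.678 CPM in the MCTS1 KO clones. ENST00000618052.1 fell from 22.1 ± 1.8 CPM to 6.05 ± 2.25 and 7.75 ± 2.75, and ENST00000379333.5 from 11.7 ± 0.393 to 3.67 ± 0.604 and 3.5 ± 0.747 (SD, n = 2 each), with log2 changes of -1.68 ± 0.22 and -1.80 ± 0.30. Of 132 transcripts called in each clone alone, 41 were higher and 83 lower in both, and 8 moved in opposite directions. The count depended on the tool and on single libraries: DESeq2 called 35 transcripts, and its own filter on low counts gave these 4 no adjusted p. Without wild type library 2, edgeR called 187, against all 4 wild type libraries with no run term 2218, and against libraries 3 and 4 alone 5294. Scaled by library totals alone, 457 were higher and 298 lower.

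In the MCTS1 KO 3710 transcripts were higher and 3344 lower in TCP-seq than in wild type libraries 3 and 4, of the same 50991 tested. ENST00000227507.2 fell from 14.1 ± 2.02 CPM to 1.02 ± 1.44 in clone #1 and 2.47 ± 1.66 in clone #2 (SD, n = 2 each), a log2 change of -3.12 ± 0.37 (SE, adjusted p = 1.7e-11). ENST00000474340.1 fell by 2.69 ± 0.36 on the log2 scale. ENST00000491235.1 rose from 2.48 ± 0.529 CPM to 13.5 ± 3.22 and 9.87 ± 3.66, and ENST00000456658.1 from 1.66 ± 0.624 to 6.24 ± 2.67 and 8.06 ± 1.49 (SD, n = 2 each). In wild type libraries 1 and 2, which were not the control here, the last pair stood at 9.77 ± 2.36 and 5.16 ± 1.41 CPM. Of 1754 transcripts called in each clone alone, 1062 were higher and 681 lower in both. Without wild type library 3 the count was 2490, and against wild type libraries 1 and 2 it was 3425, fewer than the 5294 of the eIF2D KO under the same exchange.

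TCP-seq calls in the MCTS1 KO overlapped those in the other assays of the same knockout, which use other libraries. 1266 transcripts were higher and 1341 lower in both RNA-seq and TCP-seq, where independent lists would share 608 and 651. In opposite directions 257 and 438 were called, where 507 and 781 would be shared. These overlaps were not matched by counts. The changes themselves had rho of 0.26 with those in RNA-seq and 0.26 with those in Ribo-seq. In an analysis chosen after the data had been seen, the change also followed how many TCP-seq fragments a transcript had per mRNA in wild type, taken from wild type libraries 1 and 2. In the quartile of transcripts with the lowest ratio of TCP-seq to RNA-seq the median log2 change was -0.20, and in the quartile with the highest it was 0.28 (rho = 0.29 across 50492 transcripts). Both clones showed this, with medians of -0.12 and 0.20 in clone #1 and -0.26 and 0.37 in clone #2. Per library, the highest minus the lowest quartile was 0.44 ± 0.18 (SD, n = 4) against an SD of 0.03 between the 2 wild type libraries. The KO libraries lay together by clone, at 0.33 and 0.26 in clone #1 and 0.64 and 0.52 in clone #2. The permutation p over libraries was 0.0667 (two-sided), the smallest that 15 splits allow. It takes libraries of 1 clone as independent, and no test over clones was made. Against wild type libraries 1 and 2, with the ratio taken from libraries 3 and 4, the medians were -0.10 and 0.12. The wild type ratio of Ribo-seq to RNA-seq gave nearly the same relation for the MCTS1 KO (rho = 0.27, medians -0.24 and 0.21). For the eIF2D KO it gave rho of 0.13, which lay in clone #2 (0.22, medians -0.14 and 0.12) and not in clone #1 (0, medians 0 and -0.02). With the wild type pairs exchanged rho was 0.29 for the eIF2D KO and 0.13 for the MCTS1 KO. By the ratio of TCP-seq to RNA-seq, the eIF2D KO had medians of -0.01 and 0.01 (rho = 0.01), with 0.04 and -0.05 in clone #1 and -0.03 and 0.09 in clone #2. Against wild type libraries 3 and 4 they were -0.14 and 0.12, and rho was then 0.17 for either KO, so the contrast between the knockouts depends on the wild type pair.

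**Figure D2:**
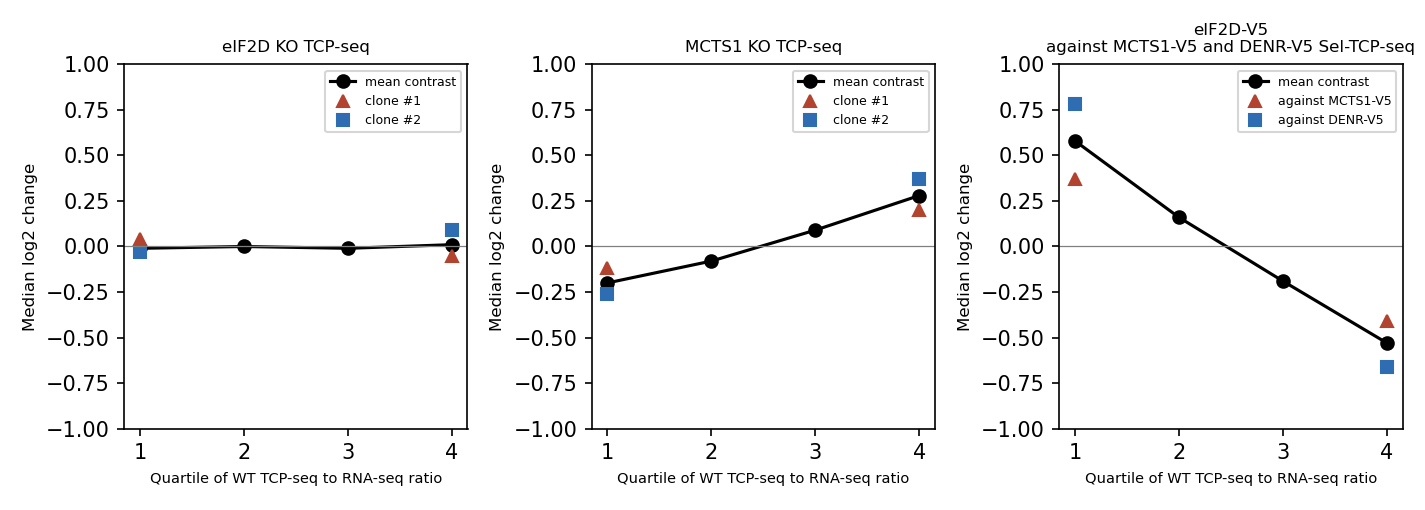
Median log2 change (y axis) over quartiles of transcripts by the ratio of TCP-seq to RNA-seq in wild type (x axis, 1 lowest), for each KO and for eIF2D-V5 selection; circles and lines give the mean contrast, triangles and squares each clone or each reference protein at the lowest and highest quartile. The MCTS1 KO medians rise from -0.20 to 0.28, those of eIF2D-V5 fall from 0.58 to -0.53, and those of the eIF2D KO lie at -0.01 and 0.01, but at -0.14 and 0.12 against the wild type libraries of the other run (not drawn).

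The effects of the 2 knockouts on TCP-seq were compared directly. The change in the eIF2D KO exceeded that in the MCTS1 KO for 727 transcripts and was below it for 1079. ENST00000227507.2 differed most, with a difference of 4.20 ± 0.46 (SE) on the log2 scale, followed by ENST00000249750.9 (3.57 ± 0.59, adjusted p = 1e-05). ENST00000590210.1 (-2.76 ± 0.61) and ENST00000451311.7 (-2.60 ± 0.52) differed most in the other direction. The latter difference was -4.54 between clones #2 and -0.65 between clones #1, which are paired only by their number. ENST00000451311.7 stood at 0.297 ± 0.42 CPM in eIF2D KO clone #2, 10.6 ± 1.23 in clone #1 and 6.23 ± 1.48 in wild type libraries 1 and 2. In the MCTS1 KO clones it stood at 19.7 ± 2.34 and 13.6 ± 0.516, against 7.62 ± 0.393 in wild type libraries 3 and 4 (SD, n = 2 each). The 2 eIF2D KO clones thus moved in opposite directions. At the same time the changes were weakly related, with Pearson's r of 0.17 and rho of 0.18 across transcripts, and from -0.05 to 0.34 between single clones. Among transcripts with a mean count of at least 50, rho was 0.327. 93 transcripts were higher and 178 lower in both, where independent lists would share 22 and 34 (Fisher's exact test, odds ratios 5.63 and 7.89, BH-adjusted p = 6.2e-33 and 1.7e-79, again over transcripts that are not independent). 30 transcripts moved in opposite directions. The difference called 247 transcripts with DESeq2, 434 without wild type library 1 and 4519 with no run term. Among transcripts with a mean count of at least 50 its direction turned, with 955 above and 623 below.

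Fragments in small-subunit complexes selected through eIF2D were spread over transcripts in other proportions than those selected through MCTS1 or DENR. The series holds no unselected library of the same cells, so only differences relative to the other selections were tested. A difference in mRNA level between the tagged cells cannot be told apart from selection. 1551 transcripts were higher and 1131 lower with eIF2D-V5 than with the mean of MCTS1-V5 and DENR-V5, of 12135 tested, and 1448 and 834 of them by at least 2-fold. ENST00000481698.1 had 89 counts with eIF2D-V5 and 0 in the 4 other libraries. Against a floor of 3 counts over those 4 libraries it was 17.2-fold higher, with a 95% exact lower limit of 13.7. ENST00000429585.5 had 92 counts against 1, a ratio of 53.4 with a 95% exact interval of 9.35 to 2130 that covers counting error only. ENST00000623551.1 and ENST00000427380.1 had 0 counts with eIF2D-V5 and 55 and 48 in the other 4 libraries. Against a floor of 3 counts over the eIF2D-V5 libraries they were 31.6-fold and 27.6-fold lower, with exact lower limits of 24.8 and 21.6. These limits leave out the spread between libraries, and ENST00000427380.1 had 3 and 20 counts in the DENR-V5 libraries. Each reference gave calls alone, 887 against MCTS1-V5 and 2312 against DENR-V5. The count was 802 without eIF2D-V5 library 2 and 4607 without MCTS1-V5 library 2.

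The difference with eIF2D-V5 ran against the number of TCP-seq fragments per mRNA in wild type, again in an analysis chosen after the data had been seen. In the quartile with the lowest ratio of TCP-seq to RNA-seq the median log2 difference was 0.58, with 712 transcripts called higher and 33 lower. In the highest quartile it was -0.53, with 124 higher and 631 lower (rho = -0.49 across 11972 transcripts). Per library, the highest minus the lowest quartile was -1.18 ± 0.54 (SD, n = 2) with eIF2D-V5, at -0.80 and -1.56, and the other 4 libraries had an SD of 0.56. MCTS1-V5 library 2, at -0.84, lay beyond eIF2D-V5 library 1. The permutation p was 0.133 (two-sided), where 0.0667 is the smallest possible. The selected libraries also differed from each other in their likeness to Ribo-seq. At 356019 counts each, the eIF2D-V5 libraries had rho of 0.550 and 0.701 with wild type Ribo-seq across 11567 transcripts, the MCTS1-V5 libraries 0.350 and 0.616, and the DENR-V5 libraries 0.350 and 0.395.

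No transcript passed the threshold between MCTS1-V5 and DENR-V5 with edgeR or with DESeq2, and 822 of 12135 had an unadjusted p under 0.05 in edgeR. The MCTS1-V5 pair was the least alike of all replicate pairs by the median ratio of its variation to counting noise, at 3.95, against 1.33 for DENR-V5. At this depth and spread, 202 transcripts were called when MCTS1-V5 library 1 was left out.

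**Figure D3:**
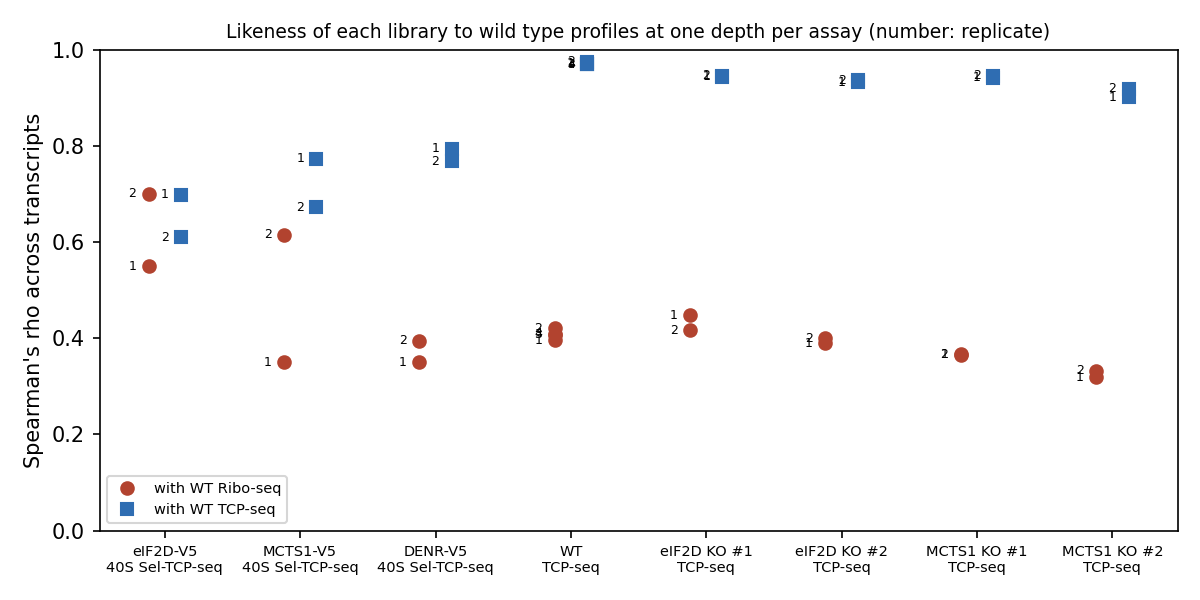
Spearman's rho (y axis) of each TCP-seq and Sel-TCP-seq library with the mean wild type Ribo-seq profile (circles) and the mean wild type TCP-seq profile (squares), by group (x axis), across 11567 transcripts; small numbers give the replicate. Libraries were thinned to 356019 counts for Sel-TCP-seq and 1609303 for TCP-seq, and wild type TCP-seq libraries are part of their own reference. The second libraries of eIF2D-V5 (0.701) and MCTS1-V5 (0.616) lie above the first (0.550 and 0.350) in likeness to Ribo-seq.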

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

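Thinning to one total, the exchange of wild type libraries and the test against the ratio of Ribo-seq to TCP-seq were chosen after the data had been seen, and for the last of these a closely related correlation was already known.

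The change differed between the MCTS1 KO clones, by a test of the difference itself, for 60455 transcripts in RNA-seq, 21453 in Ribo-seq and 6817 in translational efficiency. The 3920 transcripts called in opposite directions in RNA-seq were weighed further. The clone #1 libraries are deeper, but with all 6 libraries thinned to one total, opposite calls were still 33.3% of those called in both clones, against 33.7% before. Counting each group of shared reads once gave 32.0%, so repeated reads do not account for it either. Differences between clones that have nothing to do with MCTS1 remain open and untested, since each clone is 1 cell line, and so does a difference in library preparation between the clones.

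The change in the eIF2D KO and in the MCTS1 KO differed in TCP-seq for 1806 transcripts, and the MCTS1 KO had 7054 calls against 823. Among 6697 transcripts called in the MCTS1 KO, the median RNA-seq change was 0.110 of the median TCP-seq change. Of these, 2607 were also called in RNA-seq in the same direction and 695 in the opposite one. The TCP-seq changes were picked by their own test, which lowers this ratio, and the eIF2D KO has no RNA-seq here. Whether mRNA level accounts for the larger number of calls is therefore not decided. Depth does not account for the larger number, since at one total the MCTS1 KO had 12.9 times the calls of the eIF2D KO. Exchanging the wild type libraries of the 2 runs turned the order, with 3425 calls in the MCTS1 KO and 5294 in the eIF2D KO, a ratio of 0.647. A candidate source of the larger count is therefore wild type libraries 3 and 4, from which KO libraries of either run stand apart. The larger count was also uneven between clones. MCTS1 KO clone #2 alone gave 9758 calls and clone #1 alone 2547, against 1680 and 940 for clones #2 and #1 of the eIF2D KO. Whether a property of MCTS1 KO clone #2 adds to the count was not tested. A larger effect of MCTS1 stays possible, because the exchange also sets libraries of different runs against each other.

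The second libraries of eIF2D-V5 and MCTS1-V5 followed Ribo-seq more closely than the first, by 0.151 and 0.266 in rho at one depth, so a difference in depth does not account for it. The ratio of the second to the first library correlated across transcripts with the ratio of wild type Ribo-seq to TCP-seq, with rho of 0.565 and 0.527, and with 0.132 for DENR-V5. Fragments of elongating ribosomes in these 2 libraries may be the source, but this explanation was found from the same data and is not established by them. Both eIF2D-V5 libraries lie above both DENR-V5 libraries, so a property of eIF2D complexes, untested here, stays open beside it.

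The change also differed between the siRNAs against DENR for 32615 transcripts in RNA-seq, 12120 in Ribo-seq and 1050 in translational efficiency. It differed between the eIF2D KO clones for 4198 transcripts and between the MCTS1 KO clones for 1756 in TCP-seq.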

How the results depend on the processing

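Thinning, distinct profiles, the exchanged wild type and the selection without 2 libraries were chosen after seeing the data. Counts of calls stayed within 1.5 times with RLE factors, library totals and each distinct profile once in all 11 comparisons. Over 763 values of the 40 named transcript results under alternatives, none changed sign and 78 lost the threshold, 47 of them when 1 library was left out and 13 with DESeq2, whose own filter left 11 of those without an adjusted p. Of the 763 values, 24 for each clone number and 12 for each siRNA came from 1 clone or siRNA alone. These could not change sign, because transcripts were named only where both clones or siRNAs had the same sign. Where no cause is given below, the cause was not tested. Not run for want of gene names or libraries were the gene lists, the removal of mitochondrial, ribosomal protein and non-coding genes, all re-expression comparisons, and the difference of knockouts within 1 run.

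Counts with DESeq2 were 19290 for MCTS1 KO RNA-seq, 4229 for MCTS1 KO Ribo-seq, 6342 for siDENR Ribo-seq, 35 for eIF2D KO TCP-seq, 2225 for MCTS1 KO TCP-seq, 247 for the difference of knockouts and 1017 for eIF2D-V5. Clone #1 alone gave 55695 for MCTS1 KO RNA-seq, 19132 for Ribo-seq, 5872 for translational efficiency and 2547 for TCP-seq. Clone #2 alone gave 19664, 4167, 131 and 9758 for the same comparisons, 1680 for eIF2D KO TCP-seq and 1195 for the difference. The siRNAs alone gave 222 and 606 for siDENR translational efficiency. With no filter the counts were 1594 for MCTS1 KO translational efficiency (813 higher and 781 lower), 868 for the difference (median of all transcripts shifted to 0.106) and 4139 for eIF2D-V5 (3581 higher and 558 lower, median shifted to 0.900, from 0.030). With a mean count of at least 50, fewer transcripts were tested, and 3737 were called for MCTS1 KO TCP-seq and 586 for eIF2D-V5. Library totals moved the split of eIF2D-V5 calls to 1724 higher and 710 lower (median 0.177), of eIF2D KO calls to 457 and 298 and of siDENR RNA-seq calls to 15782 and 14260. A mean count of at least 50 turned the split of the difference to 955 and 623 and that of MCTS1 KO TCP-seq to 1764 and 1973. With no run term, 2218 were called for eIF2D KO TCP-seq and 4519 for the difference, and the wild type of the other run gave 5294 for eIF2D KO and 3425 for MCTS1 KO TCP-seq. Thinning, which removes counts, left 390 for eIF2D KO TCP-seq, 900 for the difference and 982 for eIF2D-V5. Without the second libraries of eIF2D-V5 and MCTS1-V5, 4 were called between MCTS1-V5 and DENR-V5.

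Leaving out 1 library gave 19373 to 32393 calls for MCTS1 KO RNA-seq (lowest without wild type 2), 2535 to 15372 for Ribo-seq and 417 to 4854 for translational efficiency (highest without wild type Ribo-seq 2). For siDENR it gave 14731 to 40736 in RNA-seq and 5728 to 11593 in Ribo-seq, both lowest without a control library, and 139 to 766 for translational efficiency. In TCP-seq it gave 187 to 1032 for eIF2D KO, 2490 to 7633 for MCTS1 KO and 434 to 2352 for the difference. It gave 802 to 4607 for eIF2D-V5 and 0 to 202 for MCTS1-V5 against DENR-V5. A lone library left in a group was assumed to vary like the others. The rho between MCTS1 KO and siDENR translational efficiency (0.037) ran from -0.040, without wild type Ribo-seq 2, to 0.088, and that between the knockouts in TCP-seq (0.178) from 0.105 to 0.194. With a mean count of at least 50 the latter was 0.327. With no run term it was 0.495, and shared wild type libraries alone gave 0.505 in simulation without run differences and -0.157 with them (covariances 0.0932 observed, 0.0432 and -0.023).

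The labels do not say that libraries of one replicate number belong together, and these were not treated as paired. With 2 numbers, deviations of same-numbered libraries correlated from -0.08 to 0.15 in the other fits and from 0.06 to 0.30 in Sel-TCP-seq. With the replicate block, counts were 31419, 8238 and 1191 for MCTS1 KO RNA-seq, Ribo-seq and translational efficiency, 30939, 10916 and 337 for siDENR, 1059 and 7230 for eIF2D KO and MCTS1 KO TCP-seq, 1879 for the difference, 4500 for eIF2D-V5 and 4 for MCTS1-V5 against DENR-V5. The rho values were 0.027 and 0.179 under this block.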

Other observations

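The test of the hypothesis below and its matching by counts were chosen after the data had been seen.

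The agreement of 2 clones or siRNAs is partly fixed by their shared control libraries. With 3 simulated data sets in which nothing changed, the log2 changes of the 2 MCTS1 KO clones correlated with r of 0.58 in RNA-seq, above the observed 0.15, and the covariances were 0.0302 simulated and 0.0374 observed. For the siRNAs against DENR r was 0.49 simulated and 0.47 observed, and the covariances were 0.0294 and 0.0908. In TCP-seq r was 0.58 and 0.46 for the eIF2D KO clones (covariances 0.0903 and 0.108), and 0.52 and 0.64 for the MCTS1 KO clones (0.1 and 0.262). For translational efficiency r was 0.57 and 0.28 for the MCTS1 KO (covariances 0.0542 and 0.0592), and 0.44 and 0.47 for DENR depletion (0.0588 and 0.109). In Ribo-seq it was 0.55 and 0.30 for the MCTS1 KO (0.0545 and 0.0741), and 0.45 and 0.45 for DENR depletion (0.0698 and 0.147). Part of each observed value thus comes from the controls, and the control libraries were not divided between the 2 contrasts.

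Transcripts that were higher with eIF2D-V5 were also set against the MCTS1 KO in TCP-seq. 176 were higher in both, where independent lists would share 302, and 371 were higher in the MCTS1 KO and lower with eIF2D-V5, where 221 would be shared. A further 232 were lower in the MCTS1 KO and higher with eIF2D-V5, against 158, and 125 were lower in both, against 116. Both comparisons followed the wild type ratio of TCP-seq to RNA-seq, in opposite directions (rho = 0.29 and -0.49). The overlaps are therefore not separate from that relation, and the MCTS1 KO calls depend on the wild type pair.

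A hypothesis of this work was set out when a weak correlation between the 2 comparisons was already known. It held that transcripts higher with eIF2D-V5 than with MCTS1-V5 and DENR-V5 are those that change in TCP-seq when eIF2D is lost. The excess it needs was not seen. Of 1537 transcripts higher with eIF2D-V5, 40 (2.60%) were called in the eIF2D KO, 21 of them higher and 19 lower where independent lists would share 21 and 37, against 372 of 9420 (3.95%) among those not called in the selection, a ratio of 0.659. Part of the lower share goes with fewer TCP-seq counts: weighted to the same counts in 20 bins, 2.88% of the transcripts not called in the selection were called in the eIF2D KO, a ratio of 0.905. The mean size of the log2 change was then 0.226 and 0.227. With the wild type libraries of the other run the ratio was 0.584, and 0.722 at matched counts.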
